A study of Arabidopsis thaliana with 8 samples.

How the data were processed

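Libraries were made from flowers of 2 lines, AGO1-DDH and AGO1-DAH, and grouped by line and by immunoprecipitate or input, with 2 replicates per group. Per the labels and the submitters' processing notes, the IP RNA had been trimmed with nuclease P1 and was not fragmented, the input RNA had been fragmented, and both were depleted of ribosomal RNA and sequenced on a HiSeq instrument. Per the submitters' processing notes, the authors aligned the reads with Bowtie to the TAIR10 transcripts, and neither the version of Bowtie nor its mismatch setting is given there. Per the file headers, each deposited line holds the count of times that a read sequence was observed at a transcript position, on 1-based transcript coordinates. All lines were on the sense strand. The labels do not say whether the replicates are separate plants or repeats of one sample, so they may be technical, and the p-values then measure only the spread between these samples.

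Reads per library were 945035 (DDH input, replicate 1, 1.83 reads per distinct sequence), 955777 (DDH input, replicate 2, 2.44 reads per distinct sequence), 953427 (DDH IP, replicate 1, 1.75 reads per distinct sequence), 952066 (DDH IP, replicate 2, 1.74 reads per distinct sequence), 944808 (DAH input, replicate 1, 1.93 reads per distinct sequence), 957880 (DAH input, replicate 2, 1.93 reads per distinct sequence), 930399 (DAH IP, replicate 1, 2.21 reads per distinct sequence), 999073 (DAH IP, replicate 2, 2.13 reads per distinct sequence). The totals lie close together, for a reason that the labels do not state. Every read lay in 1 locus only, so weighting of reads with several loci had no reads to act on and was not run. The processing notes do not say whether reads that fit several loci were removed or assigned to 1 of them. Input reads were 42 bases long and IP reads 50. Reads were added up per locus with Python 3.11.15 and numpy 2.4.6, giving 22819 loci, of which 22653 have a transcript in the RefSeq copy of TAIR10.1. In each library 98.9 to 99.7% of the reads in these loci matched a RefSeq transcript exactly. Reads whose first 42 bases also occur in another locus made up 7.77, 18.7, 11.2 and 9.49% of the input libraries (DDH, then DAH) and 1.93, 3.17, 3.38 and 2.06% of the IP libraries.

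Genes were tested with edgeR 4.0.16 (R 4.3.3, limma 3.58.1): filterByExpr on the 4 groups, TMM scaling, quasi-likelihood fits with a group-means design over all 8 libraries, and two-sided F tests, with the Benjamini-Hochberg adjustment over all tested genes of a comparison and a threshold of 0.05. Organelle genes were left out of the tests, and 13796 genes remained after the filter. Ribosomal and transfer RNA genes were to be left out as well, but no locus carried either class in the annotation. The locus AT2G01021 in the rDNA repeat therefore stayed in the main fit, with 0.978% and 10.9% of the reads in the DDH inputs. The common biological coefficient of variation was 0.178 and the prior degrees of freedom 17.5. TMM factors were 1.02 and 0.849 (DDH input), 1.08 and 1.06 (DDH IP), 0.991 and 1.00 (DAH input), and 1.01 and 1.01 (DAH IP). The standard error of a log2 fold change is its absolute value divided by the square root of F. The 5 comparisons were IP against input in each line, the difference of the 2 enrichments (DAH minus DDH), DAH against DDH in the inputs, and DAH against DDH in the IPs. A fold against a group with 0 reads was computed with 3 reads over that group, and a fold against a group with 1 to 3 reads has a binomial 95% interval. Intervals and floors cover counting error only. Relative to the counting error, replicates differed by a chi-square per degree of freedom of 11.4 (DDH inputs), 2.44 (DDH IPs), 3.16 (DAH inputs) and 3.38 (DAH IPs), over genes with at least 20 reads.

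Gene lists were written down before the data were examined, as were the groups, the comparisons, the tests of genes and lists, the rule for naming genes and most alternatives. The lists were miRNA targets (119 genes), TAS precursors (8), tasiRNA targets (9), small RNA pathway genes that are not themselves miRNA targets (24), floral meristem and organ identity (21), tapetum and pollen (21), photosynthesis (17), cytosolic ribosomal proteins (21), replication-dependent histones (13) and target mimics (2, IPS1 and AT4, neither of which had enough reads to be tested). From the annotation came MIRNA genes (30), pseudogenes (265) and other non-coding RNA (310). TAS4 and 35 of the miRNA targets had too few reads to be tested. Lists were tested with camera in limma on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, two-sided, adjusted over the lists of a comparison, and again with an estimated correlation. Named genes are the 8 largest increases and 8 largest decreases among called genes with a symbol, a mean CPM of at least 5 and the same sign in both replicate pairs. To these were added AGO1, DCL1, AGO2, TAS1A, TAS1B, TAS1C, TAS2 and TAS3A, and from each list or miRNA family the member with the smallest p.

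Target sites were found with Python code that scored each listed target transcript against the mature small RNA of its family (37 sequences written from general knowledge of published Arabidopsis small RNAs, with none for the TAS4 siRNA targets PAP1 and PAP2, which were not scored), with a penalty of 1 per mismatch and 0.5 per G:U pair and a limit of 5. Of 136 listed loci, 134 were scored, and 125 had both a site and a background position, drawn at random at least 200 bases away in the same transcript. Coordinates are those of a sequence match to TAIR10.1 made here. A read crossed the cleavage position if it reached at least 5 bases to both sides. Sites with at least 10 crossing reads summed over all 8 libraries (48) were tested with edgeR as above, scaled by the gene-level library sizes. This minimum was chosen after the data were seen, and so was a test of each site's share of its gene's reads. Shares have Wilson 95% intervals (alignment placement succeeded for 99.2 to 99.6% of reads). AGO1 read shares and codons were compared by two-sided Fisher's exact tests in R, which like the Wilson intervals cover counting error only. The test of AGO1 read shares was repeated on distinct sequences after the data were seen. Figures were drawn with matplotlib 3.10.9, and Biopython 1.88 and scipy 1.17.1 were used for sequences and statistics.

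The tests were tested on simulated data with the mean of each gene or site over all 8 libraries and the observed dispersions. All counts were drawn independently. Among 13796 simulated genes, 100 changed by 2-fold and 100 by 4-fold, edgeR recovered 19 and 80 for the DDH enrichment, 18 and 72 for the DAH enrichment, 0 and 36 for the difference of enrichment, 18 and 74 for the inputs and 22 and 74 for the IPs, with 8, 3, 1, 6 and 6 false calls. Absence of a call is therefore weak evidence for changes of 2-fold. Camera called a simulated list of 80 genes moved by 0.5 log2 units (1.88e-09) and did not call an unmoved list of 80 (0.744). The genes of these simulated lists were uncorrelated, whereas the correlation estimated for the real lists ran from -0.0042 to 0.722. How camera with the preset correlation performs on correlated lists was therefore not tested. Among 48 simulated sites, with 10 changed by 4-fold and 10 by 16-fold, 1 and 10 were recovered for the DDH enrichment, 4 and 10 for the DAH enrichment, 1 and 8 for the difference, 6 and 10 for the inputs and 4 and 10 for the IPs, with 0 false calls. Most real crossing reads came from the DAH IPs, so the simulated inputs and DDH IPs held more of them in sum than the real ones. Recovery at real sites may therefore be lower.

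IP and input libraries of the same replicate number come from the same lysate per the labels. Their deviations from the group means were nearly uncorrelated across 9391 genes with a mean CPM of at least 20 (-0.00446 in the DDH line and 0.0893 in the DAH line), so no block was used. Alternatives tried were DESeq2 1.42.0 size factors, DESeq2 Wald tests, scaling by total counts, no low-count filter, CPM of at least 1 in at least 2 libraries, each distinct position counted once, organelle genes kept, a replicate block, fits of the compared groups only, and each library left out in turn. For sites they were 10 bases on both sides, a penalty of at most 3, distinct positions, no AGO1, 5' ends within 1 base, and no target with the most reads, and for lists a prior count of 0.5, a block and the estimated correlation. Chosen after the data were seen were fits without the locus in the rDNA repeat (AT2G01021, 5.92 ± 6.98% of the DDH input reads), with only the reads whose first 42 bases occur in 1 locus, with the trend on GC content and transcript length removed (spline with 5 degrees of freedom), and lists with distinct positions. Raw reads were not used here, and small RNA levels were not analysed here.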

Results

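Flowers of Arabidopsis thaliana (accession Columbia) at stages 1 to 12 carried HA-tagged AGO1, the main slicing protein of the microRNA (miRNA) pathway. One line had the wild-type Asp-Asp-His catalytic residues (AGO1-DDH) and the other had the central residue changed to alanine (AGO1-DAH), a change that removes slicing. RNA recovered with each protein (immunoprecipitate, IP) and total RNA from the same lysates (input) gave 4 groups of 2 replicates, 8 strand-specific libraries in all. Each library held a similar number of aligned reads, from 930399 (DAH IP, replicate 1) to 999073 (DAH IP, replicate 2), and 13796 nuclear genes had enough reads to be tested. Chloroplast transcripts made up 15.8 ± 1.91% of the DDH input reads and 16.2 ± 0.854% of the DAH input reads, against 3.68 ± 0.533% and 4.25 ± 1.05% of the IP reads. One non-coding locus, AT1G15405, held 6.64% of the DDH input and 6.36% of the DAH input reads, and 0.769% and 0.958% of the IP reads. Across genes, replicates correlated with each other (Pearson r of log2 CPM, reads scaled to library size, 0.901 for the DDH inputs, 0.941 for the DDH IPs, 0.921 for the DAH inputs and 0.917 for the DAH IPs), whereas IP and input libraries gave r of 0.648 to 0.690. The DDH inputs were less alike than inputs of different lines, with r of 0.918 and 0.936 (DDH replicate 1 with each DAH input) and 0.906 and 0.914 (DDH replicate 2). Genes are not independent replicates, so these correlations describe the libraries only. In what follows, a log2 fold change (log2 FC) is given ± its standard error, a level in CPM or a percentage ± the standard deviation of 2 replicates, and every group has n = 2. A fold is the ratio of the reads of both replicates added up, scaled to library size, so it can differ slightly from the fitted log2 FC. Genes were called by two-sided edgeR quasi-likelihood tests at an adjusted p of 0.05.

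The transcript of AGO1 itself, which miR168 targets, was higher in the immunoprecipitate of the wild-type protein than in its input. It rose from 635 ± 312 CPM in the DDH input to 7524 ± 1029 CPM in the DDH IP (11.6-fold, log2 FC 3.56 ± 0.28, edgeR adjusted p = 4.08e-09). The TAS transcripts, non-coding precursors of trans-acting small interfering RNAs (tasiRNAs), rose as well, with log2 FC 4.52 ± 0.37 for TAS2, 4.24 ± 0.39 for TAS1C, 2.57 ± 0.38 for TAS3A and 2.00 ± 0.68 for TAS1B. TAS1A had no read in the DDH inputs and was at least 8.91-fold higher in the IP (floor of 3 reads over the group). Some of the largest increases were in arabinogalactan-protein genes, a family that was not tested as a list. AGP10 rose 97.5-fold (6.54 ± 0.51), AGP7 rose 66.4-fold (95% counting interval 18.1 to 553), AGP25 rose by 5.32 ± 0.48 and AGP27, at 0 in the inputs, was at least 9.17-fold higher. The others were the D-type cyclin gene CYCD6;1 (at least 7.38-fold, 0 in the inputs), the RING-type ligase gene SGR9, up 62.6-fold (95% counting interval 10.9 to 2503), and the cell wall xylosyltransferase gene MGP4 (5.57 ± 0.41). Among the largest decreases, the cold-response regulators CBF1 (at least 45.0-fold lower, 0 in the IPs), DREB1A, lower 98.2-fold (95% counting interval 26.7 to 818), and CBF2, lower 70.7-fold (95% counting interval 23.8 to 346), all fell. So did the zinc-finger genes STZ, lower 78.6-fold (95% counting interval 21.3 to 656), and RHL41 (-5.35 ± 0.64). ERF11, an ethylene response factor gene, the defence-related BAP1 and FKF1, a blue-light receptor gene of the flowering pathway, were at 0 in the DDH IPs and at least 17.5-fold, 13.5-fold and 23.6-fold lower.

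Of the 119 miRNA targets listed in advance, 84 were measured and 37 rose in the DDH IP, 2 fell and 45 were not called (38 and 3 when adjusted over the list alone), with a median log2 FC of 0.75. All 5 measured miR319 targets of the TCP family rose (median 2.65), as did all 3 miR171 targets (2.75) and all 3 miR160 targets (2.14). Members were TCP3 (3.14 ± 0.26), HAM3 (3.62 ± 0.32) and ARF17 (3.06 ± 0.27). Of 9 SPL genes targeted by miR156, 4 rose, among them SPL6 (3.26 ± 0.49), and 3 of 4 miR172 targets, 3 of 5 miR396 targets and 2 of 7 miR169 targets rose, led by TOE2 (1.60 ± 0.28), GRF4 (2.00 ± 0.50) and NF-YA5 (2.60 ± 0.55). In the remaining families the member with the smallest p rose for AT1G63130 (1.92 ± 0.50), NAC080 (2.51 ± 0.79), PHB (1.51 ± 0.23), LAC4 (1.26 ± 0.29) and CSD2 (1.68 ± 0.25). The same held for PHO2 (1.91 ± 0.20), MYB111 (2.52 ± 0.45), DCL1 (0.67 ± 0.22), MYB33 (0.85 ± 0.30) and AT3G45090 (0.79 ± 0.26). LAC13 was higher 8.40-fold (95% counting interval 2.64 to 42.8) on 3 input reads. The auxin receptor gene TIR1, a miR393 target, fell (-0.85 ± 0.23, adjusted p = 0.00514). The other target that fell belonged to the miR398 family of CSD2, where 1 of 3 measured members rose and 1 fell. AGO2, the target of miR403, was not called (0.36 ± 0.25, adjusted p = 0.255), and neither were IAR3 (-0.68 ± 0.28), LCR (0.33 ± 0.31), APS1 (0.37 ± 0.22), AGL16 (0.66 ± 0.53), AT5G43740 (1.08 ± 0.71), AT1G53290 (0.46 ± 0.57) and CMT3 (-0.07 ± 0.26). The list of 8 TAS precursors had 5 of 7 higher and 0 lower (6 and 0 over the list alone), with a fitted median of 4.24 and a median of 2.57 with groups at 0 set to the floor. In competitive camera tests against all other genes, two-sided with a preset correlation of 0.01, the adjusted p was 1.55e-05 for miRNA targets and 2.28e-04 for TAS precursors. Both calls were lost otherwise: adjusted p = 0.173 with an estimated correlation for miRNA targets and 0.164 for TAS precursors. The call for MYB33 ended under the DESeq2 Wald test, that for TAS1B ended with each distinct position counted once (log2 FC 1.52, adjusted p = 0.071), and that for DCL1 ended under the DESeq2 Wald test.

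Some of the fixed gene lists were lower in the DDH IP than in its input. Of 21 cytosolic ribosomal protein genes 18 fell and 0 rose (median log2 FC -1.14, RPSAA at -2.25 ± 0.24), and of 17 photosynthesis genes 13 fell and 1 rose (14 and 1 over the list alone, median -0.89, LHCA2 at -2.41 ± 0.24). Replication-dependent histone genes fell in 9 of 13 cases (10 over the list alone, median -1.30, H4-g at -2.49 ± 0.37), and tapetum and pollen genes in 9 of 17 (median -0.93, EXL4 at -1.74 ± 0.27). Annotated non-coding transcripts moved the other way: 3 of 3 measured MIRNA precursor genes rose (median 2.51). So did 24 of 41 pseudogenes, with 4 lower (26 and 5 over the list alone, median 1.64), and 50 of 95 other non-coding RNAs, with 8 lower (53 and 9, median 1.47). Camera gave adjusted p = 3.26e-09 for ribosomal proteins, 2.15e-06 for photosynthesis, 1.18e-04 for histones, 0.00185 for tapetum and pollen, 0.00265 for MIRNA genes, 1.93e-05 for pseudogenes and 1.55e-05 for other non-coding RNA. With an estimated correlation the same lists had adjusted p = 0.193, 0.254, 0.177, 0.177, 0.164, 0.177 and 0.164, so these calls rest on the preset correlation. Not called were the tasiRNA targets (1 of 4 higher and 0 lower, ARF2 at 0.72 ± 0.20, camera adjusted p = 0.621) and genes of the small RNA pathway (3 of 22 higher and 3 lower, AGO7 at 1.96 ± 0.36, adjusted p = 0.877). The floral meristem and organ identity genes were not called either (4 of 17 higher and 2 lower, SHP1 at 1.69 ± 0.30, adjusted p = 0.427). Over all genes, 2780 were higher in the DDH IP and 2496 lower, 2388 and 1951 of them by at least 2-fold. Scaling by total counts instead of TMM moved the median of all genes to 0.20 and the split to 3280 higher and 1810 lower (64.4% higher against 52.7%).

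With the slicer-defective protein, the miR173-targeted TAS transcripts had the largest fitted increases over input among the named genes. TAS1C rose from 5.85 ± 1.09 to 1465 ± 37.8 CPM (251-fold, log2 FC 7.93 ± 0.31, edgeR adjusted p = 9.06e-14), TAS2 rose 225-fold (7.76 ± 0.34), TAS1B rose 192-fold (7.50 ± 0.46) and TAS1A, with 1 input read, rose 349.9-fold (95% counting interval 62.4 to 13852). TAS3A, which miR390 targets and AGO7 cleaves, rose by 4.09 ± 0.33. AGO2 rose 20.6-fold, from 49.2 ± 9.53 to 1014 ± 9.15 CPM (4.36 ± 0.23, adjusted p = 1.04e-11), and AGO1 rose 12.6-fold, from 896 ± 29.7 to 11279 ± 803 CPM (3.65 ± 0.28), while DCL1 was not called (0.28 ± 0.22, adjusted p = 0.357). Other large increases were in the TCP gene BRC1 (at least 8.84-fold, 0 in the inputs), CYCD6;1 (at least 7.98-fold, 0 in the inputs), the guard cell regulator gene MYB60, higher 78.7-fold (95% counting interval 13.8 to 3142), and the plastid division gene YLMG1-1 (5.91 ± 0.27). Among the largest decreases, RRTF1, the calmodulin-like gene CML38, SRO5, the dehydration-response factor gene DDF1, BAP1, the cell wall gene XTH18 and the metal-transport gene PCR2 were at 0 in the DAH IPs and at least 40.1-, 30.4-, 17.1-, 14.4-, 12.5-, 8.96- and 7.79-fold lower than in the inputs. CBF2 was lower 161-fold (95% counting interval 28.5 to 6418) on 1 IP read. The calls for BAP1 and PCR2 each ended when certain single libraries were left out.

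Of the 84 measured miRNA targets, 56 rose in the DAH IP, 1 fell and 27 were not called (59 and 2 over the list alone, median log2 FC 1.52). By family, 8 of 9 miR156 targets, 6 of 7 miR169 targets, 5 of 5 miR319 targets, 4 of 4 miR164 targets and 4 of 4 miR172 targets rose. So did 4 of 5 miR396 targets, 3 of 3 miR160 targets, 3 of 3 miR171 targets and 2 of 3 miR159 targets. Their members with the smallest p were SPL3 (2.85 ± 0.23), NF-YA3 (5.02 ± 0.34), TCP3 (3.48 ± 0.25), NAC080 (2.33 ± 0.63), TOE2 (4.28 ± 0.28), GRF3 (1.54 ± 0.26), ARF17 (2.77 ± 0.27), HAM2 (2.83 ± 0.24) and MYB33 (3.09 ± 0.26). In the other families AT1G63080 (2.50 ± 0.91), PHB (2.46 ± 0.23), ARF6 (0.53 ± 0.19), AFB2 (1.37 ± 0.32), LCR (1.59 ± 0.27) and APS1 (0.76 ± 0.22) rose. So did CSD2 (1.81 ± 0.26), PHO2 (2.26 ± 0.20), LAC13 (2.35 ± 0.86), AGL16 (3.86 ± 0.41) and MYB111 (2.13 ± 0.47). The calls for AT1G63080 and LAC13 ended with a block for the replicate, whose IP and input share a lysate (adjusted p = 0.0671 and 0.0571). Not called were LAC4 (0.54 ± 0.29), AT5G60760 (1.11 ± 0.52), AT5G43740 (0.41 ± 0.76), AT1G53290 (0.08 ± 0.58) and CMT3 (-0.05 ± 0.25). The TAS precursors had 7 of 7 higher and 0 lower (median 7.50). Camera adjusted p was 6.40e-17 for miRNA targets and 1.71e-09 for TAS precursors, and 0.0382 for each with an estimated correlation. The lists that were lower with AGO1-DDH were lower here too: 9 of 21 ribosomal protein genes fell and 1 rose (10 and 1 over the list alone, median -0.55, RPS6A at -1.35 ± 0.23), and 9 of 17 photosynthesis genes fell (11, median -0.51, LHCA2 at -1.77 ± 0.24). Of the others, 8 of 13 histone genes fell (8, median -1.15, H4-g at -2.08 ± 0.37) and 9 of 17 tapetum and pollen genes fell (11, median -1.197, EXL4 at -1.62 ± 0.26). Camera gave 7.18e-04, 6.83e-05, 3.35e-04 and 1.78e-04 for these lists, and adjusted p = 0.420, 0.351, 0.231 and 0.153 with an estimated correlation. Pseudogenes were shifted up as a list with the preset correlation only (median 0.73, camera adjusted p = 0.00311, 0.351 with an estimated correlation). Of 41, 19 were higher, 3 lower and 19 not called (21 and 3 over the list alone). The same was so for other non-coding RNA (median 1.31, camera adjusted p = 7.30e-07, 0.0626 with an estimated correlation). Of 95, 38 were higher, 5 lower and 52 not called (41 and 7 over the list alone).

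Not called as lists in the DAH line were MIRNA genes (2 of 3 higher and 0 lower, median 2.66, adjusted p = 0.123) and tasiRNA targets (0 of 4 higher and 0 lower, ARF3 at 0.47 ± 0.28, 0.603). Neither were small RNA pathway genes (4 of 22 higher and 2 lower, DDL at 1.65 ± 0.36, 0.637) and floral identity genes (3 of 17 higher and 1 lower, 3 and 0 over the list alone, SHP1 at 2.08 ± 0.28, 0.242). Over all genes 2454 rose and 2155 fell in the DAH IP, 2083 and 1638 of them by at least 2-fold (edgeR). The enrichments with the 2 proteins resembled each other: 1749 genes were higher with both (494.5 expected by chance) and 1436 lower with both (389.9 expected), while 7 genes higher with AGO1-DDH were lower with AGO1-DAH and 14 went the other way. Across genes the log2 FC of the 2 lines had a Pearson r of 0.765 and a Spearman rho of 0.749, with genes not being independent replicates. For AGO1 the enrichments with the 2 proteins were not called different, but the DDH inputs held 658 and 280 reads, and the log2 FC with AGO1-DDH was 4.17 without DDH input replicate 1 and 3.15 without replicate 2. AGO2 and the miR173-targeted TAS1B were more enriched with AGO1-DAH.

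**Figure D1:**
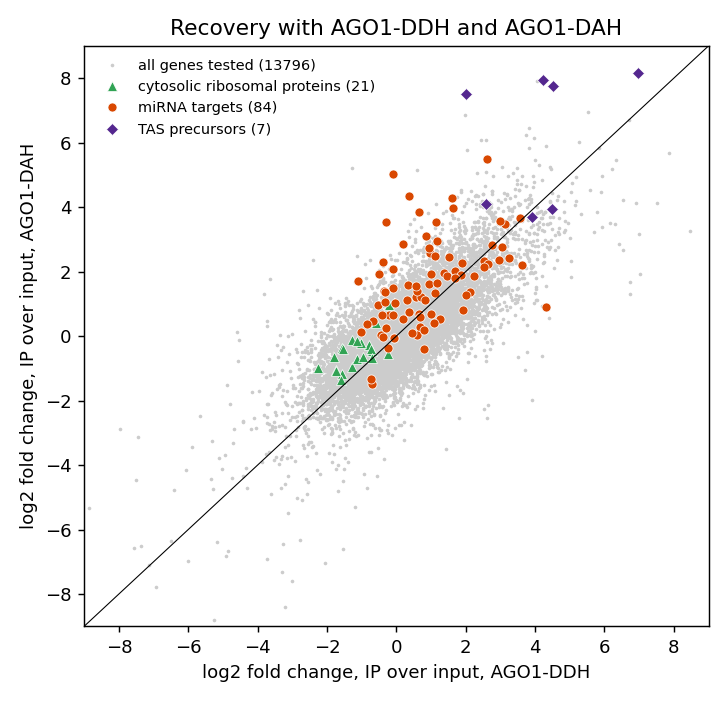
Log2 fold change of IP over input with AGO1-DDH (horizontal) against AGO1-DAH (vertical) for 13796 genes (gray points), with 84 miRNA targets (orange circles), 7 TAS precursors (purple diamonds) and 21 ribosomal protein genes (green triangles), and the line of equal enrichment. AGO2 (0.36 and 4.36) and TAS1B (2.00 and 7.50) lie above the line, and AGO1 (3.56 and 3.65) lies on it.

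The enrichment of AGO2 was 3.996 ± 0.34 log2 units greater with AGO1-DAH than with AGO1-DDH, the difference with the smallest p of all named genes (edgeR adjusted p = 8.73e-07). Its level went from 54.5 ± 3.85 to 70.3 ± 1.01 CPM in the DDH line and from 49.2 ± 9.53 to 1014 ± 9.15 CPM in the DAH line. TAS1B (5.50 ± 1.23), TAS1C (3.69 ± 0.78) and TAS2 (3.24 ± 0.77) were also more enriched with AGO1-DAH, and so were genes of the NF-YA family of CCAAT-binding factors. These were the miR169 targets NF-YA3 (5.12 ± 0.67) and NF-YA2 (3.84 ± 0.81) and their relative NF-YA6 (6.50 ± 1.28), which was not in the target list. SEN1, a senescence-associated gene, and BZO2H3, a bZIP factor gene of the starvation response, were more enriched without being listed miRNA targets (5.43 ± 1.07 and 4.08 ± 0.81). Less enriched with AGO1-DAH were ER (-4.25 ± 1.00), AAE11 (-4.15 ± 0.53), CYP71B31 (-3.68 ± 0.59), GPT2 (-3.50 ± 0.80), ASPGB1 (-3.38 ± 0.78), EXO (-3.33 ± 0.48), AGP17 (-2.95 ± 0.61) and HSP70 (-2.94 ± 0.63). Among these ER is the homologue of the enhancer of rudimentary gene, AAE11 an acyl-activating enzyme gene, GPT2 a glucose-phosphate translocator gene and EXO a brassinosteroid-responsive growth gene. Input levels enter such differences as well as IP levels. AAE11 had 14.3 and 31.1 CPM in the DDH inputs against 126 and 68.6 in the DAH inputs. Its IPs had 248 and 262 CPM (DDH) against 89.3 and 35.5 (DAH). CYP71B31 had 16.9 and 65.1 against 142 and 55.9 CPM in the inputs. In the IPs it had 162 and 140 against 27.5 and 30.1 CPM. AGO1 (0.09 ± 0.36), DCL1 (-0.39 ± 0.31) and TAS3A (1.51 ± 0.57, adjusted p = 0.209) were not called, and TAS1A, with no read in the DDH input, had no usable difference (1.19 ± 2.89). The calls for TAS1C (log2 1.12, adjusted p = 0.64), TAS2 (2.23, 0.2), NF-YA2 (2.55, 0.12) and NF-YA6 (5.18, 0.053) ended with each distinct position counted once. These 4 calls and that for TAS1B also ended without DDH input replicate 2 (adjusted p = 0.16 for TAS1B and up to 0.5 for TAS2). Those for AGO2, NF-YA3, SPL3, MYB33, TOE2, AAE11, CYP71B31 and EXO held in every alternative run.

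By list, 11 of 84 miRNA targets were more enriched with AGO1-DAH and 0 less (24 and 1 over the list alone), with a median difference of 0.48 log2 units, or 0.48 without AGO1. They were 3 of 9 miR156 targets (SPL3 at 2.65 ± 0.33), 2 of 7 miR169 targets and 2 of 4 miR172 targets (TOE2 at 2.67 ± 0.41). To these came 1 member each of the families of miR159 (MYB33 at 2.24 ± 0.41), miR393 (TIR1 at 1.23 ± 0.31), miR403 (AGO2) and miR824 (AGL16 at 3.19 ± 0.73). Among the other families ARF10 (-0.78 ± 0.40), AT1G63130 (-1.13 ± 0.69), NAC092 (2.79 ± 0.93), PHB (0.95 ± 0.32), IAR3 (1.14 ± 0.37), HAM3 (-1.42 ± 0.47) and TCP4 (0.56 ± 0.47) were not called. The same was true of LCR (1.27 ± 0.41), APS3 (-0.78 ± 0.61), GRF1 (1.38 ± 0.54), LAC4 (-0.73 ± 0.42), CSD1 (1.15 ± 0.41) and PHO2 (0.36 ± 0.28) and of ARPN (-0.61 ± 0.76), AT3G45090 (-0.59 ± 0.38), AT5G43740 (-0.67 ± 1.06), AT1G53290 (-0.38 ± 0.82), CMT3 (0.02 ± 0.36) and MYB11 (-3.40 ± 1.32). TAS precursors had 3 of 7 higher and 0 lower (4 over the list alone), all 3 being miR173 targets, and a fitted median of 1.51 (3.69 with groups at 0 set to the floor). Ribosomal protein genes were shifted up by a median of 0.67 with 1 member called (9 over the list alone, RPSAA at 1.27 ± 0.33), and photosynthesis genes by 0.37 with 1 called (1 over the list alone, LHCA4 at 1.09 ± 0.27). MIRNA genes (0 of 3 higher and 1 lower, 2 lower over the list alone) and pseudogenes (0 of 41 higher and 1 lower) were shifted down, by medians of -1.91 and -0.70 (-0.67 for pseudogenes with the floor). Camera adjusted p was 1.20e-08 for miRNA targets (0.132 with an estimated correlation), 5.53e-11 for TAS precursors (0.0265) and 2.07e-07 for ribosomal proteins (0.477). It was 0.0182 for photosynthesis (0.749), 0.0253 for MIRNA genes (0.231) and 0.0115 for pseudogenes (0.567). The calls for photosynthesis, MIRNA genes and pseudogenes each ended without several single libraries. Not called were tasiRNA targets (0.888, ARF3 at 1.09 ± 0.40), small RNA pathway genes (0.807, HST at 0.84 ± 0.39) and floral identity genes (0.747, STK at -1.09 ± 0.53). Nor were tapetum and pollen genes (0.527, GRP17 at -0.73 ± 0.30), histones (0.486, H4-b at 0.78 ± 0.40) and other non-coding RNA (0.527). In all, 140 genes were more and 96 less enriched with AGO1-DAH, each by at least 2-fold, and 1941 had an unadjusted p below 0.05. Leaving out a single library moved the total of 236 to between 77 and 434. Scaling by total counts moved the median of all genes to -0.19 and gave 70 more and 109 less enriched genes (39.1% more against 59.3%), and the calls for TIR1 (1.05, adjusted p = 0.12), LHCA4 and RPSAA ended. The last 2 also ended with the replicate block (adjusted p = 0.0645 and 0.0637).

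In the inputs, no gene was called between the lines (edgeR, 0 called, smallest adjusted p = 0.659, 487 genes at an unadjusted p below 0.05). AGO1 was at 635 ± 312 CPM in the DDH and 896 ± 29.7 CPM in the DAH input (0.50 ± 0.26, edgeR adjusted p = 1), AGO2 differed by -0.15 ± 0.26 and DCL1 by 0.24 ± 0.23. Among TAS transcripts the differences were TAS1B (-0.40 ± 1.00), TAS1C (0.48 ± 0.64), TAS2 (-0.31 ± 0.69) and TAS3A (0.38 ± 0.49), none called. TAS1A, TAS3B and TAS3C had 0 reads in the DDH inputs and 1, 2 and 3 in the DAH inputs, too few for a fold. Across the miRNA target families the largest of the representative differences, MYB11 with 2 and 4 reads left aside, were SPL6 (1.54 ± 0.60), NAC1 (1.1998 ± 0.78), AT1G63130 (1.03 ± 0.56), MYB65 (0.95 ± 0.43), NF-YA2 (-0.89 ± 0.66), HAM3 (0.75 ± 0.41), GRF3 (0.69 ± 0.31) and TCP2 (0.62 ± 0.35). DESeq2 also called 0 genes, and the fit without a low-count filter called 6. Without DDH input replicate 1 the count was 25, and edgeR recovered only 18 of 100 simulated 2-fold changes in this comparison. Of the lists, photosynthesis genes were lower in the DAH input by a median of -0.30 with 0 members called (camera adjusted p = 1.49e-04, adjusted p = 0.917 with an estimated correlation), a call that ended without DDH input replicate 2 (0.672). Camera adjusted p was 0.411 for miRNA targets and 0.751 for TAS precursors, and no other list was called. Without DDH input replicate 1, ribosomal protein genes were called between the inputs (camera adjusted p = 3.77e-06).

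Between the immunoprecipitates, NF-YA6 was higher with AGO1-DAH 120.3-fold (95% counting interval 32.9 to 999), NF-YA3 by 5.10 ± 0.34 and AGO2 14.4-fold (3.85 ± 0.22, edgeR adjusted p = 2.13e-10). All 7 measured TAS precursors were higher, among them TAS1B (5.10 ± 0.34), TAS1C (4.17 ± 0.22), TAS1A (3.60 ± 0.31), TAS3C (3.58 ± 0.83), TAS2 (2.93 ± 0.21) and TAS3A (1.89 ± 0.26). The list median was 3.58 (camera adjusted p = 1.50e-14, 0.0153 with an estimated correlation). SEN1 was higher 34.1-fold (95% counting interval 9.08 to 288). Lower with AGO1-DAH were the late embryogenesis genes LEA3, lower 27.6-fold (95% counting interval 4.58 to 1128), and LEA7, lower 8.57-fold (95% counting interval 2.64 to 44.1), and the secondary wall regulator gene NST1, lower 11.4-fold (95% counting interval 2.84 to 99.7). So were the miRNA precursor gene MIR398c (-2.71 ± 0.34), the abscisic acid signalling gene AFP1 (-2.66 ± 0.68) and the abscisic acid hydroxylase gene CYP707A3 (-2.51 ± 0.63). The others were SDR1 (-2.57 ± 0.68) and the flavonol regulator gene MYB11, a miR858 target (-2.56 ± 0.58). Of 84 miRNA targets 29 were higher and 1 lower (37 and 3 over the list alone, median 0.58, camera adjusted p = 2.37e-14, 0.0532 with an estimated correlation). They included 6 of 7 miR169, 5 of 9 miR156, 4 of 4 miR172, 3 of 4 miR393 and 2 of 3 miR159 targets. Among them were SPL3 (2.21 ± 0.22), MYB33 (2.48 ± 0.24), TOE2 (2.32 ± 0.23), AFB2 (1.69 ± 0.32), AGL16 (3.10 ± 0.36) and NAC092 (2.71 ± 0.61). Further ones were IAR3 (1.43 ± 0.26), LCR (1.63 ± 0.26), GRF3 (1.66 ± 0.26), CSD1 (1.41 ± 0.30), TCP4 (0.86 ± 0.25) and PHB (0.75 ± 0.21). Not called were AGO1 (0.58 ± 0.25), DCL1 (-0.16 ± 0.21), ARF16 (0.58 ± 0.24), PPR1 (0.82 ± 0.55), HAM3 (-0.67 ± 0.24), APS1 (0.63 ± 0.21) and LAC4 (-0.47 ± 0.27). Neither were PHO2 (0.35 ± 0.19), LAC13 (-0.33 ± 0.62), AT3G45090 (-0.72 ± 0.25), AT5G43740 (-0.75 ± 0.66), AT1G53290 (-0.29 ± 0.54) and CMT3 (0.20 ± 0.25). The calls for TCP4 and PHB ended under scaling by total counts, and the call for TAS3C ended without DDH IP replicate 2 (3.04, adjusted p = 0.18). That for NST1 ended with the replicate block (adjusted p = 0.0568).

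Ribosomal protein genes were shifted up in the DAH IP as a list with the preset correlation only (median 0.54, camera adjusted p = 1.65e-07, 0.409 with an estimated correlation). Of 21, 7 were higher, 0 lower and 14 not called (10 higher over the list alone, RPS15AA at 1.36 ± 0.26). MIRNA genes (2 of 3 lower, 2 lower and 1 higher over the list alone, median -1.18, 0.0418, 0.265 with an estimated correlation) were lower. That call ended with the replicate block (0.0526) or without any single library other than DDH IP 2 and DAH input 2. Pseudogenes were shifted down as a list with the preset correlation only (median -0.58, camera adjusted p = 0.00144, 0.409 with an estimated correlation). Of 41, 4 were lower, 2 higher and 35 not called (6 and 2 over the list alone). The list call ended without DAH IP replicate 2. Photosynthesis genes (1 higher, 1 lower of 17, LHCA4 at 0.95 ± 0.19, 0.655), tapetum and pollen genes (1 of 17 lower, GRP17 at -0.82 ± 0.22, 0.596) and other non-coding RNA (4 higher, 1 lower of 95, 0.596) were not called as lists. The same was so for tasiRNA targets (ARF3 at 0.76 ± 0.28, 0.992), small RNA pathway genes (HST at 0.69 ± 0.26, 0.655), floral identity genes (SHP1 at 0.73 ± 0.24, 0.992) and histones (HTR9 at 0.63 ± 0.35, 0.507). Over all genes 467 were higher and 389 lower in the DAH IP, 329 and 256 by at least 2-fold, and 2803 had an unadjusted p below 0.05. With total-count scaling the split was 324 higher and 433 lower (42.8% higher against 54.6%), and the DESeq2 Wald test called 480 genes.

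Reads crossing the predicted cleavage position of a target, between the bases opposite miRNA positions 10 and 11, can come only from RNA that had not been cut there. The most such reads came from TAS1C, whose miR173 site was crossed by 409 of 1256 and 510 of 1386 reads in the 2 DAH IPs, or 32.6% (Wilson 95% interval 30.0 to 35.2%) and 36.8% (Wilson 95% interval 34.3 to 39.4%). In the DDH IPs it was crossed by 0 of 78 and 1 of 76. At the miR168 site of AGO1 the DAH IPs had 236 of 9352 and 337 of 11006 reads, 2.52% (Wilson 95% interval 2.22 to 2.86%) and 3.06% (Wilson 95% interval 2.76 to 3.40%). The DDH IPs had there 141 of 6512 and 142 of 7713, 2.17% (Wilson 95% interval 1.84 to 2.55%) and 1.84% (Wilson 95% interval 1.56 to 2.17%). TAS1B had 168 of 359 and 247 of 538 in the DAH IPs and 9 of 18 and 5 of 9 in the DDH IPs, where so few reads leave the share uncertain (Wilson 95% intervals 29.0 to 71.0% and 26.7 to 81.1%). TAS2 had 130 of 769 and 140 of 806 against 0 of 104 and 1 of 113, and TAS1A 122 of 177 and 142 of 232 against 0 of 14 and 0 of 21. Crossing reads were more numerous in the DAH than in the DDH IPs at the miR156 sites of SPL3 (log2 FC 2.76 ± 0.61, edgeR adjusted p = 4.52e-05), SPL11 (3.16 ± 0.66, 1.47e-05) and SPL5 (1.59 ± 0.64, 0.0321) and at the miR172 site of AP2 (2.42 ± 0.62, 5.16e-04). They were not called at SPL9 (0.92 ± 0.65, 0.218) or AGO1 (1.08 ± 0.53, 0.0751). Such counts also rise when more of the whole transcript is recovered, so alone they do not show retention at the site. By share of the gene's reads (DDH, then DAH IPs), SPL3 had 7 of 102, 13 of 96, 66 of 424 and 65 of 446. SPL5 had 9 of 40, 11 of 72, 24 of 105 and 34 of 125. SPL11 had 6 of 58, 6 of 56, 53 of 171 and 51 of 168. AP2 had 2 of 60, 17 of 95, 51 of 157 and 47 of 135. Wilson 95% intervals of the 2 lines overlapped at SPL3, SPL5 and AP2 but not at SPL11. Summed over 125 target transcripts with a site, crossing reads made up 7.26% (1709 of 23539, Wilson 95% interval 6.94 to 7.60%) and 7.87% (2038 of 25894, 7.55 to 8.20%) of the reads in the DAH IPs. In the DDH IPs they made up 2.01% (280 of 13958, 1.79 to 2.25%) and 1.97% (305 of 15444, 1.77 to 2.21%). The inputs had 1.54% (1.22 to 1.96%) and 1.85% (1.44 to 2.38%) in the DDH line and 1.503% (1.17 to 1.93%) and 1.56% (1.24 to 1.96%) in the DAH line. The 110 miRNA targets with a site had, taken alone, 4.17% (3.90 to 4.46%) and 4.42% (4.15 to 4.69%) in the DAH IPs. They had 2.08% (1.85 to 2.34%) and 1.98% (1.77 to 2.22%) in the DDH IPs. Over all targets the group means were 7.57 ± 0.432% for the DAH IP, 1.99 ± 0.0220% for the DDH IP, 1.70 ± 0.215% for the DDH input and 1.53 ± 0.0395% for the DAH input. At a background position drawn at random at least 200 bases away the means were 0.989%, 1.34%, 1.199% and 1.34%. Reads were 50 bases long in the IPs and 42 in the inputs, and with the first 42 bases of each read the DAH IP shares were 4.48% and 5.28%.

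Of the 48 sites with at least 10 crossing reads summed over all 8 libraries, 31 had more crossing reads in the DAH IP than in its input (median log2 FC 3.95). In the DDH IP this held for 1, that of AGO1 (4.43 ± 0.72, edgeR adjusted p = 2.60e-07, median over sites 0.54), a call that ended with the replicate block (0 sites), and 24 had more in the DAH IP than in the DDH IP (median 2.46). None was lower in any of these. Most crossing reads came from the DAH IPs, so a site could pass the minimum of 10 through them alone. This selection can raise the counts and medians of every comparison that includes the DAH IPs. Without either DAH IP library, the 31 and the 24 both became 0. In the inputs 0 sites were called by edgeR (2 at an unadjusted p below 0.05), and 0 for the difference of enrichment (7 at an unadjusted p below 0.05, median 2.99). DESeq2 was not run on sites. A test of each site's share of its own gene's reads called 0, 0 and 6 sites in the DAH IP against input, the DDH IP against input and the IP contrast. Within 50 bases of a cleavage position, the fraction of read 5' ends falling exactly on it was 0.127% (1 of 788) and 0.240% (2 of 834) in the DDH IPs and 0.810% (31 of 3825) and 0.993% (42 of 4229) in the DAH IPs. The 3' products of cleavage start there. If they stayed in the IP with intact 5' ends, more cutting with AGO1-DDH would give the reverse order. Whether they did was not tested, and the IP RNA had been trimmed with nuclease P1. No test was used for this measure. Within 1 base of the position, the share in the DAH input was no lower than in the DAH IP. On build TAIR10.1, the miR173 sites are those of TAS1C (chromosome 2, 16537890 to 16537911, minus strand, non-coding RNA, exon 1, GTGATTTTTCTCTACAAGCGAA) and TAS1A (chromosome 2, 11722081 to 11722102, minus strand, non-coding RNA, exon 1, GTGATTTTTCTCTACAAGCGAA). The other 2 are in TAS1B (chromosome 1, 18549660 to 18549681, minus strand, non-coding RNA, exon 1, GTGATTTTTCTCAACAAGCGAA) and TAS2 (chromosome 2, 16539991 to 16540012, minus strand, non-coding RNA, exon 1, GTGATTTTTCTCTCCAAGCGAA). The miR168 site lies in AGO1 (chromosome 1, 17891529 to 17891549, minus strand, coding sequence, exon 2, TTCCCGAGCTGCATCAAGCTA) and the miR172 site in AP2 (chromosome 4, 17403019 to 17403039, plus strand, coding sequence, exon 10, CTGCAGCATCATCAGGATTCT). For miR156 the sites are in SPL3 (chromosome 2, 14305878 to 14305897, plus strand, 3' UTR, exon 2, TTGCTTACTCTCTTCTGTCA) and SPL5 (chromosome 3, 5140598 to 5140617, minus strand, 3' UTR, exon 2, CCGCTCTCTCTCTTCTGTCA), both in the 3' untranslated region. Coding sites of miR156 are in SPL11 (chromosome 1, 9503618 to 9503637, plus strand, coding sequence, exon 4, GTGCTCTCTCTCTTCTGTCA) and SPL9 (chromosome 2, 17589066 to 17589085, plus strand, coding sequence, exon 3, GTGCTCTCTCTCTTCTGTCA).

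**Figure D2:**
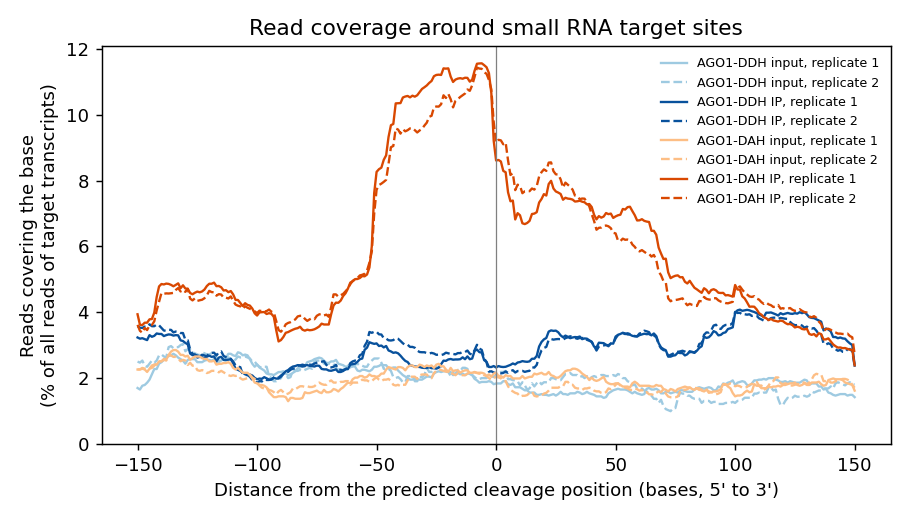
Reads covering each base from 150 bases 5' to 150 bases 3' of the predicted cleavage position, as a percentage of all reads of the target transcripts, with 1 line per library (solid, replicate 1; dashed, replicate 2). The DAH IPs peak at the position, above the DDH IPs and the inputs. Reads crossing it with at least 5 bases on both sides, a stricter count than the plotted coverage, made up 7.26% and 7.87% in the DAH IPs.

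**Figure D3:**
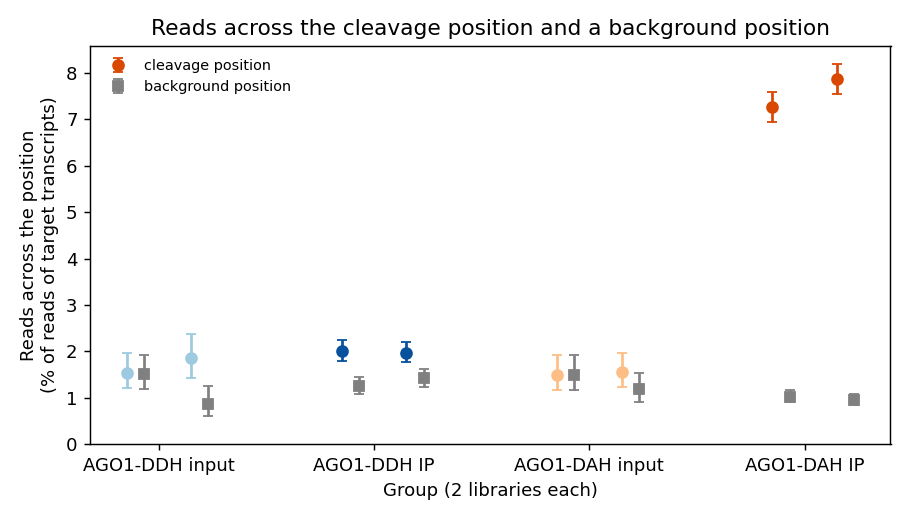
Percentage of target-transcript reads crossing the predicted cleavage position (circles) or a background position (gray squares), 1 point per library with Wilson 95% intervals. The DAH IPs stand at 7.26% and 7.87%, and the DDH IPs at 2.01% and 1.97%.

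Depth over the catalytic codons of AGO1 differed between the lines at the residue that the mutation changes. The depth over the codon of the second catalytic aspartate (residue 846), relative to the flanking sequence, was 0.0944 and 0.0660 in the DAH IPs and 1.251 and 1.42 in the DDH IPs. At the first aspartate (residue 760) the ratio was 2.68 and 2.94 in the DAH IPs and 3.11 and 2.84 in the DDH IPs, and at the histidine (residue 986) it was between 0.479 and 0.518 in all 4 IPs. In the inputs the ratio at residue 846 was 1.40 and 0.210 in the DAH line and 0.359 and 1.84 in the DDH line. Counting distinct reads, the DAH IPs had 4 over residue 846 against 32 over residue 760, and 4 against 39, while the DAH inputs had 6 against 6 and 2 against 7 (two-sided Fisher's exact tests, p = 0.00923 and 0.275, reads and not plants being the units). With the replicates added up, the DAH IPs had 8 against 71 and the DAH inputs 8 against 13 (exact p = 0.00466). The same test in the DDH line gave an exact p = 0.796. AGO1 reads were placed here by exact match to the wild-type sequence. Reads carrying the mutated codon were therefore not counted, whatever the mismatch setting of the alignment, which is not given. Counts over residue 846 in the DAH line are thus of reads with the wild-type codon only. At the miR168 site, reads whose first 42 bases crossed the cleavage position made up 2.13% and 2.73% of AGO1 reads in the DAH IPs and 0.434% and 0.726% in the DAH inputs (two-sided Fisher's exact p = 6.29e-04 and 4.65e-04, covering counting error only, with PCR copies counted as separate reads). In the DDH line they made up 1.87% and 1.41% of the IP reads, and 10 of 658 (1.52%) and 0 of 280 input reads (exact p = 0.648 and 0.0340). Counting each distinct sequence of the first 42 bases once, at most 33 starts can cross the position, which limits how far the share in the IPs can rise. The DAH IPs had 22 of 1475 and 24 of 1600 crossing, against 3 of 429 and 5 of 405 in the inputs (exact p = 0.332 and 0.819). The DDH IPs had 20 of 1364 and 21 of 1502, against 7 of 429 and 0 of 160 (exact p = 0.821 and 0.254).

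**Figure D4:**
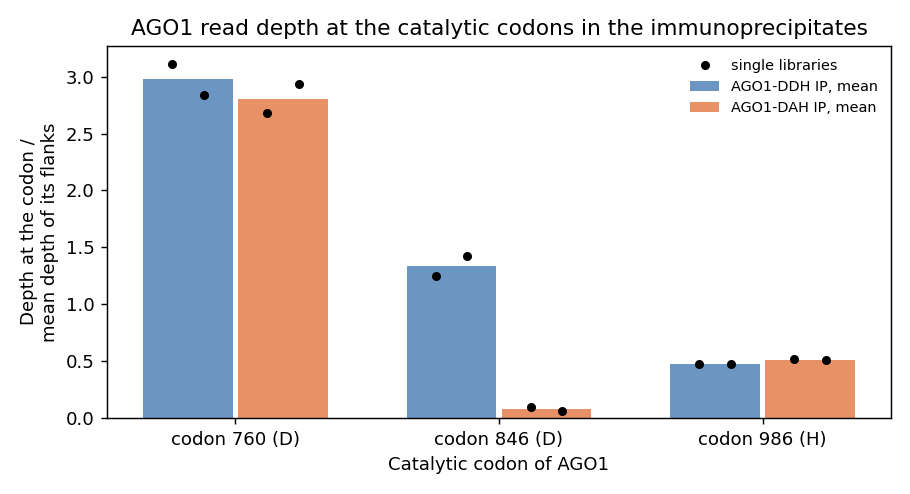
Read depth over 3 catalytic codons of AGO1 relative to the flanking sequence in the immunoprecipitates (bars, mean of 2 libraries; points, single libraries). At residue 846 the DAH IPs lie at 0.0944 and 0.0660 and the DDH IPs at 1.251 and 1.42. Only reads that match the wild-type sequence exactly are counted.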

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

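Of the tests described in this part, those of the share of reads crossing cleavage positions, of capture at the miR168 site in each line, of recovery of the transgene transcript and of the TAS list with the GC and length trend removed or distinct positions counted, by median and by camera, were chosen only after the result was seen. The tables of genes, lists and sites had been seen before the others were run. The enrichment over input differed between the 2 AGO1 proteins for 236 genes (77 to 434 with a single library left out), and the difference itself was tested by an interaction term in edgeR. This is why each of the following was picked for a closer look. By list, the median log2 difference of enrichment (DAH minus DDH) was 0.48 for miRNA targets, 0.48 for miRNA targets without AGO1, 1.51 for TAS precursors, 0.67 for ribosomal proteins, 0.37 for photosynthesis, -1.91 for MIRNA genes and -0.70 for pseudogenes. The TAS median was 3.69 with groups at 0 set to the floor, as 3 of its 7 members had a group without reads. With an estimated correlation the camera adjusted p was 0.132 for miRNA targets with or without AGO1, 0.477 for ribosomal proteins, 0.749 for photosynthesis, 0.231 for MIRNA genes and 0.567 for pseudogenes, so these calls were lost, and 0.0265 for TAS precursors. By gene, the difference was NF-YA6 (6.50 ± 1.28), TAS1B (5.50 ± 1.23), SEN1 (5.43 ± 1.07), NF-YA3 (5.12 ± 0.67), BZO2H3 (4.08 ± 0.81), AGO2 (3.996 ± 0.34), NF-YA2 (3.84 ± 0.81), TAS1C (3.69 ± 0.78), TAS2 (3.24 ± 0.77), AGL16 (3.19 ± 0.73), TOE2 (2.67 ± 0.41), SPL3 (2.65 ± 0.33), MYB33 (2.24 ± 0.41), RPSAA (1.27 ± 0.33), TIR1 (1.23 ± 0.31) and LHCA4 (1.09 ± 0.27) for those more enriched with AGO1-DAH. For those less enriched it was ER (-4.25 ± 1.00), AAE11 (-4.15 ± 0.53), CYP71B31 (-3.68 ± 0.59), GPT2 (-3.50 ± 0.80), ASPGB1 (-3.38 ± 0.78), EXO (-3.33 ± 0.48), AGP17 (-2.95 ± 0.61) and HSP70 (-2.94 ± 0.63). A signal outside the tests was that of mitochondrial transcripts, which made up a mean of 1.05% of IP reads, above the 0.533% (DDH) and 0.604% (DAH) of the inputs.

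The first pattern weighed is that miRNA target and TAS transcripts were more enriched with AGO1-DAH, where the call for miRNA targets rests on the preset correlation. A candidate explanation is that uncut target RNA stays at the small RNA site when slicing is lost, and reads crossing the cleavage position made up at least 7.26% of target reads in each DAH IP, against 2.01% and 1.97% in the DDH IPs. TAS transcripts contributed to this: the miRNA targets alone had 4.17% and 4.42% against 2.08% and 1.98%, and the test of each site's share called 0 sites for the DAH enrichment and 6 for the IP contrast. Read 5' ends exactly at the cleavage position, where 3' cleavage products start, were a larger share in the DAH than in the DDH IPs. That order was not tested. More cutting with AGO1-DDH would give the reverse only if cut products stayed in the IP with intact 5' ends. The IP RNA was trimmed with nuclease P1, so this measure cannot decide. For the miRNA targets the median difference was 0.594 (standard error 0.186) with the trend on GC content and transcript length removed. It was 0.328 (0.154) with each distinct position counted once, where PCR copies of single fragments would have left it near 0. Both medians lay more than 2 standard errors above 0, the limit that the rule written before these tests set for arguing against the 2 technical explanations. These standard errors treat the targets as independent, whereas the estimated inter-gene correlation of the list was 0.0608. They may thus be too small, so the medians alone cannot decide. With the trend removed, camera called the miRNA target list with the preset correlation (adjusted p = 4.41e-10) but not with an estimated correlation (0.0762). For the TAS list the median difference of enrichment was 1.36 (1.14) without the GC and length trend and 1.01 (0.93, 6 members measured) with distinct positions. Of the 7 members in the main fit, 3 had a group with 0 reads. These medians and standard errors therefore rest partly on fitted values without a usable difference, and cannot decide. Camera called the list with the preset correlation (adjusted p = 4.41e-10 and 8.50e-07) but not with an estimated correlation (0.0762 and 0.152). So these explanations and a biological one cannot be told apart there. Between the IPs alone the TAS medians were 3.16 (0.51) and 2.23 (0.41), which argues against both (camera with an estimated correlation 0.0302 and 0.0563).

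The second pattern is that the AGO1 transcript stood far above input with both proteins, by 11.6-fold and 12.6-fold. Whether capture at the miR168 site adds to this cannot be told apart from its absence in either line: the exact p in the weaker replicate was 6.29e-04 (DAH) and 0.648 (DDH) with PCR copies counted as separate reads, and 0.819 and 0.821 with distinct reads, where a ceiling of 33 starts limits the IP share, so neither count decides. Extra recovery of the transgene's own transcript, for example through the protein being made on it, may add to the signal. Only exact matches to the wild-type sequence were counted, so reads with the mutation are left out. Relative to residue 760, reads with the wild-type codon 846 were scarcer in the DAH IPs than in their inputs with the replicates added up (exact p = 0.00466). By replicate the exact p was 0.00923 and 0.275, so extra recovery too cannot be told apart from equal recovery. How much AGO1 RNA comes from the transgene in the DDH line stays open, because its sequence does not differ from that of the endogenous gene at these codons.

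The third pattern is that 5276 (DDH) and 4609 (DAH) transcripts differed between IP and input. GC content and transcript length together accounted for at most 0.737% of the variance of enrichment across genes, and at least 94.6% of the calls stayed after the trend was removed. Reads shared between loci at the shorter input read length are argued against as well, since at least 98.0% of the calls kept their direction with only reads whose first 42 bases occur in 1 locus. The IPs were trimmed with nuclease and the inputs fragmented, a difference that coincides with the comparison, and an unbound control is not analysed here, so binding by AGO1 and RNA handling may both contribute. No biological explanation was tested for this pattern.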

How the results depend on the processing

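Fits without the rDNA-repeat locus, with reads whose first 42 bases occur in 1 locus, with the GC and length trend removed, lists with distinct positions and the site share tests were chosen only after the data were seen. No called gene, list or site turned its direction, but with total-count scaling most calls pointed the other way for the difference of enrichment (70 more and 109 less, against 140 and 96) and for the IP contrast (324 and 433, against 467 and 389). Where a value moved, the cause was not tested. Of the called named genes, 10 of 47 (DDH enrichment), 7 of 45 (DAH enrichment), 16 of 24 (difference of enrichment) and 17 of 33 (IP contrast) lost their call in at least 1 alternative, mostly without a single library, when the group's lone sample is assumed to vary like the other groups. In alternatives that keep all libraries and were planned, 5, 4, 7 and 3 lost it. Genes called for the DDH enrichment numbered 3699 with the DESeq2 Wald test and 5502 with distinct positions (main value 5276), and for the DAH enrichment 3083 and 4592 (4609). For the IP contrast the DESeq2 Wald test called 480 genes and the fit of the compared groups only called 1364 (856). Without a low-count filter 411 genes were called for the difference of enrichment (236) and 6 between the inputs (0). A block on the lysate, or on the replicate number between the lines, gave 5208 and 4535 calls for the enrichments, 225 for their difference, 0 for the inputs and 826 for the IP contrast. Correlations of the deviations between lines were -0.0546 (inputs) and 0.0332 (IPs), and the block ended the calls for AT1G63080 and LAC13 (DAH enrichment), for LHCA4 and RPSAA (difference), for NST1 and for the MIRNA list (0.0526, IP contrast), and lowered the AGO1 site to no call in the DDH line, with no other call of a named gene or list changed. Leaving out each library in turn gave 3702 to 5418 calls (DDH enrichment), 3088 to 5009 (DAH enrichment), 77 to 434 (difference, 434 without DDH input 1, 77 without DDH IP 1, 106 without DDH IP 2, 81 without DAH input 1, 152 without DAH input 2, 82 without DAH IP 2), 0 to 25 (inputs, 25 without DDH input 1, 2 without DDH input 2, 4 without DAH input 2) and 194 to 1268 (IP contrast, 194 without DDH IP 1, 305 without DDH IP 2, 490 without DAH IP 1, 289 without DAH IP 2). TAS1C, TAS2, TAS1B, NF-YA2 and NF-YA6 lost the difference call without DDH input 2 (adjusted p = 0.34, 0.5, 0.16, 0.2 and 0.29).

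List calls lost with an estimated correlation (edgeR counts, camera adjusted p) were all those for the DDH enrichment (0.164 to 0.254, with miRNA targets at 0.173 and TAS precursors at 0.164). For the DAH enrichment they were those of tapetum and pollen (0.153), photosynthesis (0.351), ribosomal proteins (0.420), histones (0.231), pseudogenes (0.351) and other non-coding RNA (0.0626). For the difference they were those of miRNA targets (0.132), photosynthesis (0.749), ribosomal proteins (0.477), MIRNA genes (0.231) and pseudogenes (0.567), for the inputs that of photosynthesis (0.917), and for the IP contrast those of miRNA targets (0.0532), ribosomal proteins (0.409), MIRNA genes (0.265) and pseudogenes (0.409). The lists of miRNA targets and TAS precursors kept their calls without any single library. The photosynthesis difference ended without DDH input 2 (0.377), DAH input 2 (0.0654) or DAH IP 2 (0.406) and without the GC and length trend (0.140). That of pseudogenes ended with distinct positions (0.114) or without DDH input 1 (0.0592), DDH IP 2 (0.0577), DAH input 2 (0.242) or DAH IP 2 (0.344). That of MIRNA genes ended without DDH input 2 (0.194), DDH IP 1 (0.128), DAH input 2 (0.0654), DAH IP 1 (0.0857) or DAH IP 2 (0.0579). In the IP contrast the MIRNA call ended without DDH input 1 (0.0877), DDH input 2 (0.108), DDH IP 1 (0.215), DAH input 1 (0.0802), DAH IP 1 (0.116) or DAH IP 2 (0.0940). The pseudogene call for the DAH enrichment ended without DAH IP 1 (0.0525) and that for the IP contrast without DAH IP 2 (0.280). Called sites for the DDH enrichment were 3 with 10 bases on both sides, 2 with distinct positions, and 0 without AGO1, with the replicate block or by the share test. For the difference 10 bases gave 2 sites (0), and the share test gave 0 for the DAH enrichment and 6 for the IP contrast (24). Over single libraries left out, sites numbered 0 to 3 (DDH), 0 to 32 (DAH), 0 to 3 (difference), 0 (inputs) and 0 to 27 (IP contrast), being 0 without either DAH IP for the DAH enrichment and the IP contrast. The mean share of crossing reads with 10 bases on both sides was 1.196% (DDH input), 1.29% (DDH IP), 0.958% (DAH input) and 4.66% (DAH IP). With a penalty of at most 3 it was 2.03% (DDH IP) and 8.003% (DAH IP), with distinct positions 2.05% (DDH IP), 1.69% (DAH input) and 5.38% (DAH IP), and without AGO1 1.72% (DAH input) and 10.9% (DAH IP). The share of 5' ends within 1 base of the cleavage position was 2.36% (DDH input), 1.248% (DDH IP), 3.96% (DAH input) and 3.86% (DAH IP). At the exact position it was 0.409% (DDH IP) with distinct positions, and 0.315% (DDH IP) and 1.13% (DAH IP) without AGO1, the target with the most reads.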

Other observations

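The genes of this paragraph lie outside the naming rule and were chosen after their values were seen, and the tests of sites among them were written down before their output. The ubiquitin-conjugating enzyme gene UBC10 had the same adjusted p for the difference of enrichment as AGO2 (3.12 ± 0.27 log2 units more with AGO1-DAH, edgeR adjusted p = 8.73e-07). It rose by 0.51 over input with AGO1-DDH and by 3.63 with AGO1-DAH. Further genes more enriched with AGO1-DAH were PORB (3.14 ± 0.35), SIP2 (2.79 ± 0.35), DYL1 (3.12 ± 0.40), DIN10 (2.79 ± 0.43), ERD5 (2.46 ± 0.36) and LHB1B1 (3.08 ± 0.45): a protochlorophyllide reductase gene, a raffinose hydrolase gene, a dormancy-associated gene, a dark-inducible gene, a proline dehydrogenase gene and a light-harvesting protein gene. For PORB and SIP2 the DDH IP lay below its input (-3.43 and -2.63), and the DAH IP lay near its input (-0.29 and 0.17). Genes less enriched with AGO1-DAH included MYBR1 (-1.99 ± 0.33), GTL1 (-1.99 ± 0.33), CIP1 (-2.21 ± 0.33), LRX3 (-2.37 ± 0.38) and FD1 (-2.10 ± 0.31). None of these is a listed miRNA target. No gene at all was called between the inputs, so the lack of a call does not show that the input levels of these genes were equal. Those of UBC10 were alike (272 and 278 CPM in DDH, 280 and 296 in DAH). Those of SIP2 (931 and 772 against 428 and 574) and LRX3 (49.4 and 48.8 against 138 and 73.7) were less so, and input levels enter the difference of enrichment.

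It may be that transcripts outside the lists were more enriched with AGO1-DAH because they are targets of the same small RNAs. Of 123 unlisted transcripts called higher, 0 had a site with a penalty of 3 or less, against 58 of 13230 not called (0.438%) and 0 of 94 called lower. The odds ratio was 0 (95% interval 0 to 7.14, two-sided Fisher's exact p = 1), so with so few sites expected, unlisted small RNA targets and no such targets cannot be told apart. That reading was chosen after the value was seen: an odds ratio of at most 1 had been set beforehand as speaking against this explanation, and it was met only within its interval. The limit of 3 also leaves out known kinds of target: the best site of the unlisted NF-YA6 and of the listed NF-YA3 has a penalty of 4.0, and that of NF-YA2 of 4.5.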
